A study of Rattus norvegicus with 21 samples.

How the data were processed

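Total RNA of rat bone marrow mesenchymal stem cells was sequenced in 21 libraries, 3 for each of 7 groups. The authors trimmed reads with SOAPnuke 2.2.1, aligned them to Rnor_6.0 with HISAT2 2.2.1 and to a gene set of known and newly assembled coding and noncoding transcripts with Bowtie2 2.4.5 (up to 200 alignments per read), and quantified genes with RSEM 1.3.1 in its reverse-stranded setting (forward probability 0), per the submitters' processing notes, which also name DESeq2 1.34.0. The annotation release was not given in the sources used here. The extraction protocol took DNA and RNA from the same sample. The labels do not say how replicates were made or whether Control and the SFSN groups were processed together.

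The table in hand held 4 values per gene and library. Per the file headers these were the expected count of RSEM, the FPKM, the TPM and a normalized count, a signal that the authors had divided by a library factor. The expected counts, rounded to whole numbers, were the main measurement (84.4% of nonzero values were whole as deposited). The FPKM served with the counts to derive each gene's effective length, the TPM served an alternative test, and the authors' normalized counts served to recover their library factors. The authors' group means were not used here. The table held 9998 genes in alphabetical order up to Map2k1, of which 233 had no count in any library. Genes later in the alphabet were not analysed here. For 26 genes whose symbol had been turned into a date, the symbol was restored from the gene ID. Of the gene IDs 8666 matched the reference of gene names, and 7478 symbols were identical to it. Library totals over these genes were 8113600 to 8934239 counts.

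Groups were taken from the sample labels, with all 21 libraries and replicate numbers unused. Genes were filtered with filterByExpr, which left 6659, and scaled by TMM. A quasi-likelihood model with 1 mean per group (14 residual degrees of freedom, biological coefficient of variation 11.8%) was fitted in edgeR 4.0.16 under R 4.3.3. Each SFSN group was compared with Control, with the mean of the other 5 SFSN groups, and pairwise with each other SFSN group. Genes with an adjusted p (Benjamini-Hochberg, edgeR) under 0.05 were called. The SE is the log2 fold change divided by the square root of its F statistic. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists and the 6 contrasts of a family, and again with an estimated correlation. Counts of list members called used the adjusted p over all genes, and were repeated adjusted over the list alone. Principal components used the 500 most variable genes. Replicate pairs were compared by chi-square over genes with at least 20 counts. For genes with 1 to 3 counts per Control library the ratio of summed counts was given with an exact binomial interval. To gauge the effect of shared controls, 20 sets of all 21 libraries, Control included, were simulated without group differences. They were drawn from the mean of Control and the fitted spread between replicates.

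The 29 fixed lists were 6 lineage lists (endothelial, osteoblast, tendon, fibroblast, neuron, adipocyte), 7 of other cell types (mesenchymal stem cell surface and niche, macrophage and leukocyte, erythroid, smooth muscle, chondrocyte, glia and Schwann cell, epithelial) and 16 of processes (cell cycle, p53 and senescence, inflammatory cytokine, interferon response, unfolded protein and amino acid response, heat shock, hypoxia and glycolysis, cholesterol synthesis, Notch pathway, TGF-beta and YAP target, BMP target, Wnt target, immediate early, synaptic and ion channel, extracellular matrix remodelling, mitochondrial respiration). They were written from general knowledge, and 287 of their 502 genes were in the table. A further list came from a marker column that the submitters had set beside the table, with 36 entries, 34 distinct and 24 in the table. Genes were named in the report by a fixed rule. It took the 6 marker genes of the fates, the 8 highest and 8 lowest genes per group against Control with a mean of at least 10 CPM in the higher group and no overlap of libraries, up to 4 members per list, all members of a group's own lineage list, 10 genes per direction called in all 6 groups, and the 5 highest and 5 lowest per group against the other SFSN groups, by the same limits and with no overlap with the 15 other SFSN libraries.

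The method was tested on simulated data with the mean counts of all 21 libraries and the spread of each gene in the fit of all groups. Genes of at least 2 CPM were changed in SFSN-EC. The wider spread within SFSN-EC itself was thus not simulated. Of 67 genes changed 1.5-fold 36 were called (53.7%), of 67 changed 2-fold 61 (91%), and of 66 changed 4-fold 64 (97%), with 8 false calls (4.7%). Against the mean of the other SFSN groups these were 55 (82.1%), 64 (95.5%) and 64 (97%), with 7 false calls (3.7%). A list of 12 genes raised 1.5-fold was called, and none of the unchanged lists was.

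Alternatives were DESeq2 1.42.0, limma voom, limma on log2 TPM with 1 or 0.1 added (genes with TPM of at least 1 in 3 libraries), median-ratio size factors (RLE), no low-count filter, a filter of 1 CPM in 3 libraries, a replicate block, only the 6 libraries compared, 1 library left out in turn, and fry as list test. Later additions were total counts as library size, the authors' library factors, leaving out SFSN-EC 1 and SFSN-Neu 2, and taking out each library's trend with gene length. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.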

Results

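RNA was sequenced from rat bone marrow mesenchymal stem cells, the stromal cells of the marrow that can form bone, cartilage and fat, with a wild-type genotype. The 21 libraries fell into 7 groups of 3. Control carried no treatment label, and the other 6 groups carried the treatment label SFSN together with the cell fate after which the submitters named each group: endothelial cells for SFSN-EC, osteoblasts for SFSN-Ot, tendon cells for SFSN-TC, fibroblasts for SFSN-FB, neuron-like cells for SFSN-Neu and adipocytes for SFSN-Adipo. The series title speaks of self-feedback synaptic networks and of stem cells that take several fates, so the questions asked here were which genes differed between each SFSN group and Control, and whether genes of the named fate set a group apart from the other SFSN groups. The gene table in hand held 9998 genes, in alphabetical order up to Map2k1, and genes later in the alphabet were not analysed here. Between 8113600 and 8934239 counts per library fell on those genes, which is part of each library and not its depth. By the deposited TPM values they made up 38.9% to 41.6% of a library. Of the 9998 genes, 6659 had enough counts to be tested. Fold changes are on the log2 scale ± SE, relative to the median gene, with 3 libraries against 3 Control libraries, or 3 against the 15 libraries of the other 5 SFSN groups. "Rose" and "fell" are used only of genes and lists past an adjusted p of 0.05. The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The groups, the tests, the gene lists and the rule for naming genes were chosen before the data were examined.

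Control stood apart from all 18 SFSN libraries. The first principal component of the 500 most variable genes, with 26.9% of their variance, placed the 3 Control libraries between 22.2 and 24.1 and the SFSN libraries between -7.2 and -0.1. The second component, with 16.4%, ran from SFSN-TC (-14.2 to -12.2) to SFSN-FB (7.6 to 13.1). Spearman correlations across genes were 0.981 to 0.996 within a group, 0.967 to 0.979 between a Control and an SFSN library, and 0.974 to 0.994 between libraries of different SFSN groups. Genes are not independent replicates, so these correlations only describe the libraries. A pair of libraries differed from their own group by more than the others did: SFSN-EC 1, with a chi-square per degree of freedom of 42.58 and 41.43 to its replicates, which differed from each other by 2.16, and SFSN-Neu 2, with 21.56 and 23.98, where its replicates differed by 2.83. No replicate pair lay within sampling noise, so all 21 libraries were counted. The 10 most abundant genes took 21.4% to 21.5% of the counts in Control and 17.9% to 20.6% in the SFSN libraries.

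**Figure D1:**
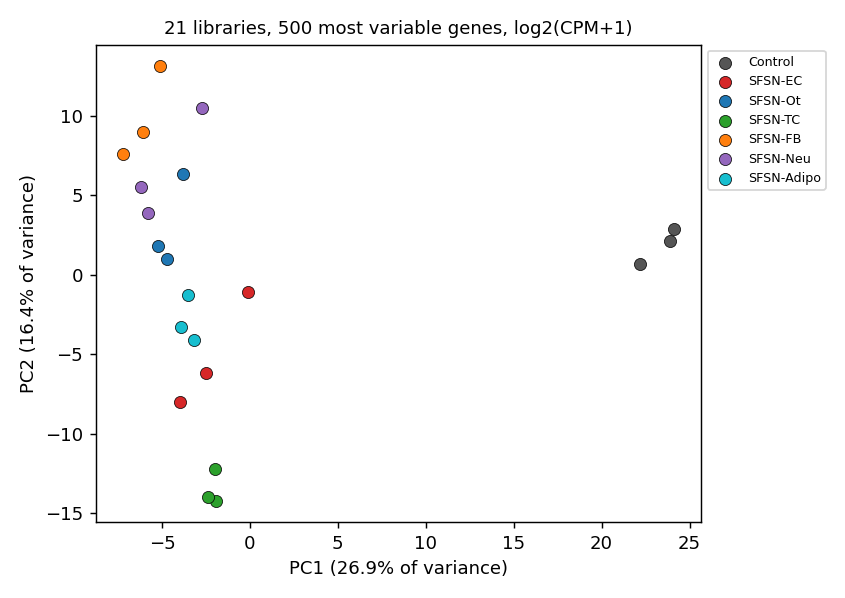
Principal component scores of the 21 libraries (x axis, component 1 with 26.9% of the variance, y axis, component 2 with 16.4%, both in score units without a physical dimension), 1 point per library, coloured by group. The 3 Control libraries lie at 22.2 to 24.1 on the first component and the 18 SFSN libraries at -7.2 to -0.1.

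For each fate, 1 well-known marker gene had been fixed to be reported first: Pecam1, Runx2, Scx, S100a4, Map2 and Pparg. Map2, which encodes a microtubule protein of neuronal dendrites, was in the table. The library names of SFSN-Neu begin with MAP2, and what that name stands for is not given in the sources used here. Pecam1, Runx2, Scx, S100a4 and Pparg were not analysed here. Map2 stood at 28.8 ± 1.63 CPM in Control (SD, n = 3) and at 13.5 ± 1.52 CPM in SFSN-Neu, a log2 fold change of -1.10 ± 0.14 (adjusted p = 7.57e-06, edgeR). It fell in the other 5 SFSN groups as well, by -0.75 ± 0.14 in SFSN-FB and by -1.30 ± 0.15 in SFSN-EC at the extremes. SFSN-Neu did not differ from the other SFSN groups in Map2 by more than the spread between replicates (-0.08 ± 0.12, adjusted p = 0.742).

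In SFSN-EC, endothelial genes were lower than in Control. Of the 5 endothelial genes tested, 3 fell: Flt1, a receptor for vascular endothelial growth factor, by -2.71 ± 0.16, Erg, an endothelial transcription factor, by -0.75 ± 0.15, and Egfl7, a protein secreted by endothelial cells, by -0.46 ± 0.12. Icam2 (-0.21 ± 0.38) and Esam (-0.01 ± 0.26) were not called. Cdh5, Kdr, Emcn and Ecscr had too few counts to be tested. They had 0 to 7 counts per SFSN-EC library and 0 to 3 per Control library. The list's median was -0.46 (adjusted p = 0.0115), and the call was lost with adjusted p = 0.132 with an estimated correlation. Egfl7 was not called under total-count scaling (adjusted p = 0.115), with only the 6 libraries of both groups (adjusted p = 0.0787) or without SFSN-EC 3 (adjusted p = 0.0544). Counts of list members called were the same adjusted over the list alone, here and in what follows, unless another count is given.

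Genes that rose by much in SFSN-EC included the following. Cxcl13, a chemokine that attracts B cells, rose by 5.08 ± 0.24, the neutrophil chemokine Cxcl1 by 4.89 ± 0.13, Ibsp, the bone sialoprotein gene, by 4.59 ± 0.10, and Acan, which encodes the cartilage proteoglycan aggrecan, by 3.77 ± 0.14. Of 14 adipocyte genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone). Their median was 1.11 (adjusted p = 5.49e-12, and adjusted p = 0.0051 with an estimated correlation). Adipoq, the gene of the fat hormone adiponectin, rose by 4.35 ± 0.17, the fatty acid carrier Fabp4 by 4.11 ± 0.24 and the glycerol channel Aqp7 by 4.53 ± 0.26. Among 12 inflammatory cytokine genes 8 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was 1.03 (adjusted p = 9.58e-11, and adjusted p = 0.0111 with an estimated correlation). Notch pathway genes rose too, 6 of 8 with 1 lower, among them Heyl (1.05 ± 0.09), Hes1 (0.94 ± 0.08) and the ligand Jag1 (0.86 ± 0.07). The median of the list was 0.85 (adjusted p = 3.23e-05, and adjusted p = 0.0111 with an estimated correlation). Osteoblast genes had 4 higher and 1 lower of 8 and a median of 0.66 (adjusted p = 3.94e-05, and adjusted p = 0.00613 with an estimated correlation). Macrophage and leukocyte genes had 7 of 13 higher and a median of 0.28 (adjusted p = 0.0258), a call lost with adjusted p = 0.227 with an estimated correlation and without SFSN-EC 1 (adjusted p = 0.0954). Cell cycle genes had a median of 0.38 with 9 of 12 higher (adjusted p = 0.003, and adjusted p = 0.0226 with an estimated correlation), led by the mitotic kinesin Kif11 (0.72 ± 0.10). Among the genes that fell were Dio3, an enzyme that inactivates thyroid hormone (-3.72 ± 0.22), Egfl6 (-2.88 ± 0.19), the gap junction gene Gjb2 (-2.50 ± 0.25), the aminopeptidase gene Lvrn (-2.12 ± 0.09), the protease receptor gene F2rl1 (-2.10 ± 0.16), the muscle enolase Eno3 (-2.06 ± 0.17) and the complement regulator Cd55 (-2.03 ± 0.07). In all, 1179 genes rose and 1036 fell in SFSN-EC, 446 of them at least 2-fold.

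Set against the other SFSN groups, the endothelial list was not apart in SFSN-EC (median -0.07, adjusted p = 0.532), and Flt1 differed by -0.07 ± 0.13. SFSN-EC differed from the mean of the other SFSN groups in adipocyte, immediate early and cholesterol genes. These lists moved the same way in SFSN-TC, the group that differed from SFSN-EC in the fewest genes (111). Their medians in SFSN-TC were 0.68, 0.34 and -0.27, so they were not particular to SFSN-EC. In SFSN-EC 6 of the 14 adipocyte genes rose (8 adjusted over the list alone), among them Fabp4 (1.19 ± 0.14) and the fatty acid transporter Cd36 (0.47 ± 0.08). Without SFSN-EC 1 the calls of Adipoq (0.29) and Cfd (0.20) were lost. The list had a median of 0.33 (adjusted p = 6.01e-07, and adjusted p = 0.0193 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, rose by 1.28 ± 0.06. Immediate early genes, the first to respond to many stimuli, had a median of 0.26 with 6 of 12 higher (7 adjusted over the list alone), led by Fos (0.47 ± 0.04), Dusp1 (0.45 ± 0.03) and Jun (0.44 ± 0.07), at adjusted p = 7.02e-14 and adjusted p = 0.000187 with an estimated correlation. Cholesterol synthesis genes fell, 8 of 11 (9 adjusted over the list alone), with a list median of -0.29 (adjusted p = 1.45e-15, and adjusted p = 0.000152 with an estimated correlation). The elastin gene Eln fell by -0.56 ± 0.04. Genes of macrophages and leukocytes were lower with them, at a median of -0.18 (adjusted p = 1.22e-06, and adjusted p = 0.023 with an estimated correlation), and the receptor gene Csf1r stood at -0.52 ± 0.04. The BMP target list had a median of 0.19 with 3 of 10 higher (5 higher and 1 lower adjusted over the list alone, adjusted p = 2.09e-05, and adjusted p = 0.0336 with an estimated correlation), with Atoh8 at 0.82 ± 0.06. A total of 211 genes rose and 189 fell, and the 400 became 250 without SFSN-EC 2 and 253 without SFSN-EC 3. SFSN-EC 1, the library that stood apart from its group, is 1 of the 3 behind these values, and 645 genes were called with the gene-length trend of each library taken out.

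In SFSN-Ot, osteoblast genes were higher than in Control and higher than the mean of the other SFSN groups. Against Control, 4 of the 8 osteoblast genes tested rose and 1 fell. Ibsp rose by 5.18 ± 0.10, from 8.06 to 293 CPM, the alkaline phosphatase gene Alpl by 1.83 ± 0.10 and Dmp1, a matrix protein of bone, by 1.55 ± 0.22, while the collagen gene Col1a1 fell by -0.25 ± 0.05. The transcription factor gene Dlx5 was the remaining member called higher (0.41 ± 0.16, adjusted p = 0.0465), but its call was lost with RLE size factors (adjusted p = 0.052), without a low-count filter (adjusted p = 0.0593) and without SFSN-Ot 1, 2 or 3 (adjusted p = 0.0622, 0.0638 and 0.155), Control 1 (0.27, adjusted p = 0.224) or Control 3 (adjusted p = 0.0653). Col1a2 (-0.03 ± 0.29), Ifitm5 (0.78 ± 0.57) and Dlx3 were not called. The median was 0.60 (adjusted p = 1.4e-06, and adjusted p = 0.0051 with an estimated correlation), and 0.36 without SFSN-Ot 2 (adjusted p = 2.41e-07). Relative to the other SFSN groups 4 members rose, Dmp1 by 0.67 ± 0.15, Ibsp by 0.49 ± 0.06, Dlx3 by 0.40 ± 0.09 and Alpl by 0.33 ± 0.07. Dlx3 was thus higher than in the other SFSN groups without a call against Control. The median of the list was 0.29 (adjusted p = 0.00776, and adjusted p = 0.0336 with an estimated correlation). Without SFSN-Ot 3 the calls of Alpl (adjusted p = 0.0809) and Dlx3 (adjusted p = 0.0721) were lost. The median over Control was not particular to SFSN-Ot. It was 0.66 in SFSN-EC, 0.61 in SFSN-TC, 0.58 in SFSN-FB, 0.35 in SFSN-Neu and 0.34 in SFSN-Adipo.

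Beyond the bone genes, large rises in SFSN-Ot were those of Cxcl13 by 5.25 ± 0.24, Adipoq by 3.91 ± 0.18, Acan by 3.86 ± 0.14, Cxcl1 by 3.36 ± 0.13, Enpp2, which encodes the secreted enzyme autotaxin, by 3.21 ± 0.17, and the acid-sensing channel Asic3 by 2.89 ± 0.18. The glutathione transferase gene Gsta5 rose by 5.38 ± 0.38, a value that is uncertain because related genes of its family can share reads. The adipocyte list had 8 higher and 1 lower of 14 and a median of 0.49 (adjusted p = 0.000137), and the call was lost with adjusted p = 0.055 with an estimated correlation. Inflammatory cytokine genes rose, 9 of 12 with 1 lower and a median of 0.83 (adjusted p = 3.02e-07, and adjusted p = 0.0254 with an estimated correlation). The macrophage and leukocyte list had 5 higher and 2 lower of 13 (5 and 3 adjusted over the list alone) and a median of 0.26 (adjusted p = 0.028), a call lost with adjusted p = 0.232 with an estimated correlation. Genes that fell included Dio3 (-4.63 ± 0.23), Egfl6 (-2.82 ± 0.19), the calcium channel gene Cacna1i (-2.80 ± 0.33), Flt1 (-2.68 ± 0.16) and the protease inhibitor gene A2m (-1.89 ± 0.15). Against Control 1347 genes rose and 1285 fell, 539 of them at least 2-fold.

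SFSN-Ot also had higher cholesterol synthesis and TGF-beta and YAP target genes than the mean of the other SFSN groups. Immediate early and adipocyte genes fell there in part. Of 11 cholesterol synthesis genes 7 rose (8 adjusted over the list alone), with Insig1 at 0.64 ± 0.04 and Hmgcs1 at 0.54 ± 0.03. The list had a median of 0.28 (adjusted p = 1.03e-14, and adjusted p = 0.000152 with an estimated correlation). TGF-beta and YAP targets had 5 of 8 higher, among them Bhlhe40 (0.66 ± 0.07), Lats2 (0.43 ± 0.03) and Ctgf (0.33 ± 0.04). The median of the list was 0.29 (adjusted p = 4.17e-06, and adjusted p = 0.00219 with an estimated correlation). Adipocyte genes fell, 6 of 14 (7 adjusted over the list alone), with Cd36 at -1.35 ± 0.09, Fabp4 at -0.88 ± 0.16 and a median of -0.20 (adjusted p = 2.23e-05, and adjusted p = 0.034 with an estimated correlation). Chac1, a glutathione-degrading enzyme of the stress response, fell by -1.53 ± 0.10, Fos by -1.05 ± 0.04 and Jun by -1.04 ± 0.08. The immediate early list as a whole had 4 higher and 5 lower of 12 (5 and 7 adjusted over the list alone) and a median of -0.12 (adjusted p = 0.012), and its call was lost with adjusted p = 0.0981 with an estimated correlation. Cell cycle genes fell slightly, 4 of 12 (5 adjusted over the list alone). Their median was -0.15 (adjusted p = 0.0146, and adjusted p = 0.0444 with an estimated correlation). Macrophage and leukocyte genes had a median of -0.38 with 7 of 13 lower and 1 higher (adjusted p = 0.00182), a call lost with adjusted p = 0.119 with an estimated correlation, and lysozyme Lyz2 stood at -0.57 ± 0.07. Of all genes, 526 rose and 473 fell, and the 999 became 657 without SFSN-Ot 1, 662 without SFSN-Ot 2 and 656 on log2 TPM values with limma.

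In SFSN-TC, tendon genes did not move together. Of 12 tested, 3 rose and 6 fell against Control (4 and 6 adjusted over the list alone). Egr1, a transcription factor of the immediate early class with a role in tendon, rose by 2.48 ± 0.10, Egr2 by 0.78 ± 0.10 and Lum, the gene of the matrix proteoglycan lumican, by 0.72 ± 0.03, while the collagen gene Col14a1 fell by -1.67 ± 0.13, Comp, a cartilage and tendon matrix protein, by -1.60 ± 0.25, and Bgn, Col5a2, Col11a1 and Fmod, the fibromodulin gene, by -0.32 to -0.36. The median was -0.22, the mean -0.01 and the direction of the test upward (adjusted p = 0.525). Relative to the other SFSN groups, Egr2 (0.68 ± 0.07) and Egr1 (0.64 ± 0.07) rose, Fmod fell by -0.62 ± 0.07 and Dcn by -0.15 ± 0.05, a call lost without SFSN-TC 1, 2 or 3 (adjusted p = 0.176, 0.14 and 0.0761). On log2 TPM Dcn stood at -0.06, without a call. The list was not apart (2 higher and 2 lower, median 0.00, adjusted p = 0.802).

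Fat genes rose in SFSN-TC over Control, as did Cxcl1 (4.96 ± 0.13) and Cxcl13 (4.44 ± 0.24). Adipoq rose by 5.07 ± 0.17, from 1.47 to 49.7 CPM, Aqp7 by 5.04 ± 0.26 and Fabp4 by 4.24 ± 0.24. The adipocyte list had 10 higher and 1 lower of 14. Its median was 1.44 (adjusted p = 3.39e-14, and adjusted p = 0.0051 with an estimated correlation). Osteoblast genes rose as well, 4 of 8 with 1 lower, among them Ibsp (4.68 ± 0.10) and Alpl (1.40 ± 0.10). The list had a median of 0.61 (adjusted p = 4.31e-05, and adjusted p = 0.00613 with an estimated correlation). Notch pathway genes had a median of 1.11 with 6 of 8 higher (7 adjusted over the list alone), among them Heyl (1.42 ± 0.09), Hey1 (1.16 ± 0.13) and Hes1 (1.14 ± 0.08), at adjusted p = 4.15e-07 and adjusted p = 0.0051 with an estimated correlation. The immediate early genes Fos (2.95 ± 0.06), Fosb (2.29 ± 0.37) and Jun (1.64 ± 0.09) rose, with 7 higher and 4 lower of 12 and a median of 0.81 (adjusted p = 3.55e-05, and adjusted p = 0.0156 with an estimated correlation). Inflammatory cytokine genes had 6 higher and 1 lower of 12 (7 and 1 adjusted over the list alone) and a median of 0.30 (adjusted p = 0.001), a call lost with adjusted p = 0.125 with an estimated correlation. Dio3 (-3.77 ± 0.22), Gjb2 (-3.31 ± 0.27), Egfl6 (-3.19 ± 0.20), Flt1 (-2.57 ± 0.16), Cd55 (-2.35 ± 0.07) and Esm1 (-2.30 ± 0.06) were among the genes that fell. Against Control 1285 genes rose and 1249 fell, 528 of them at least 2-fold.

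Relative to the mean of the other SFSN groups, SFSN-TC had higher fat, Notch and immediate early genes and lower macrophage and leukocyte genes. Adipocyte genes were higher than in the other groups, 10 of 14 (10 higher and 1 lower adjusted over the list alone), with Fabp4 at 1.35 ± 0.13 and a median of 0.68 (adjusted p = 7.02e-14, and adjusted p = 0.00169 with an estimated correlation). Gpd1, an enzyme that makes the glycerol backbone of fat, rose by 1.37 ± 0.09 and Aqp7 by 1.41 ± 0.12. Notch pathway genes rose, 6 of 8. Their median was 0.34 (adjusted p = 1.22e-06, and adjusted p = 0.0039 with an estimated correlation), and immediate early genes 8 of 12 (8 higher and 1 lower adjusted over the list alone), with Fosb at 1.94 ± 0.24 and a median of 0.34 (adjusted p = 1.24e-16, and adjusted p = 0.000152 with an estimated correlation). Cholesterol synthesis genes fell, 6 of 11 (8 adjusted over the list alone). Their median was -0.27 (adjusted p = 4.01e-06, and adjusted p = 0.00506 with an estimated correlation). The list of macrophages and leukocytes had 6 of 13 lower (7 adjusted over the list alone), a median of -0.30 (adjusted p = 2.81e-07, and adjusted p = 0.0172 with an estimated correlation) and Csf1r at -1.19 ± 0.04. Single genes that fell included the lipoxygenase Alox5 (-2.68 ± 0.20), Irg1, the itaconate-producing enzyme of macrophages (-1.92 ± 0.10), the chemokine Ccl20 (-1.82 ± 0.16) and Adam8 (-1.75 ± 0.07). Inflammatory cytokine genes had a median of -0.39 with 7 of 12 lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p = 3.94e-05), a call lost with adjusted p = 0.0693 with an estimated correlation. The 1036 genes called (509 higher, 527 lower) became 647, 599 and 644 without SFSN-TC 1, 2 and 3. Long genes stood higher relative to short ones in SFSN-TC, by 0.29 against Control and 0.22 relative to the other SFSN groups between the longest and the shortest of 5 equal classes of genes, and 899 of the 1036 were also called with the gene-length trend taken out.

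In SFSN-FB, fibroblast genes moved in both directions. Against Control, Cd34, a surface protein of stromal and vascular progenitors, rose by 2.02 ± 0.42 and Fap, the fibroblast activation protein gene, by 0.72 ± 0.09, while Lox, which crosslinks collagen, fell by -1.33 ± 0.06, the fibronectin gene Fn1 by -0.60 ± 0.10 and Col6a1 by -0.16 ± 0.04. The other 5 of the 10 tested were not called, among them Col3a1 (0.08 ± 0.06) and Ddr2 (0.03 ± 0.13). The median was 0.02, the mean 0.09 and the direction of the test downward (adjusted p = 0.47). Relative to the other SFSN groups, the collagen VI genes Col6a3 (-0.41 ± 0.09), Col6a1 (-0.24 ± 0.03) and Col6a2 (-0.21 ± 0.03) fell, with a list median of -0.09 (adjusted p = 0.139). The list passed with SFSN-EC 1 and SFSN-Neu 2 left out (median -0.10, adjusted p = 0.0237).

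Inflammatory genes rose in SFSN-FB. Against Control, 11 of 12 inflammatory cytokine genes rose and 1 fell. Their median was 1.68 (adjusted p = 3e-16, and adjusted p = 0.0051 with an estimated correlation). Cxcl1 rose by 5.11 ± 0.13 and Ccl20 by 2.84 ± 0.21. Cxcl2, a neutrophil chemokine with 1 to 2 counts per Control library, was 68.5 times its Control level (95% counting interval 29.1 to 212, exact binomial, counting error only), compared with 55.9 times (23.7 to 173) in SFSN-TC and 15.3 times (6.3 to 48.4) in SFSN-Ot. Cxcl13 rose by 5.79 ± 0.23, Ibsp by 5.13 ± 0.10, Enpp2 by 3.67 ± 0.17, Acan by 3.62 ± 0.14, Acsbg1, a lipid-activating enzyme, by 3.36 ± 0.24, and Ass1, an enzyme of arginine synthesis, by 3.18 ± 0.22. Macrophage and leukocyte genes had 6 higher and 1 lower of 13 (7 and 1 adjusted over the list alone), with Csf1r at 1.20 ± 0.05, the integrin gene Itgam at 1.20 ± 0.15 and a median of 0.50 (adjusted p = 9.63e-05), a call lost with adjusted p = 0.0564 with an estimated correlation. Osteoblast genes had 3 higher and 2 lower of 8, with Alpl at 1.76 ± 0.10 and Dlx3 at -1.06 ± 0.13. The median of the list was 0.58 (adjusted p = 0.000581, and adjusted p = 0.0145 with an estimated correlation). The adipocyte list had 8 higher and 2 lower of 14 and a median of 0.51 (adjusted p = 0.0239), a call lost with adjusted p = 0.212 with an estimated correlation. Adipoq rose by 2.42 ± 0.19. Dio3 (-5.18 ± 0.25), Cacna1i (-3.31 ± 0.35), Kctd21 (-2.77 ± 0.14), Flt1 (-2.68 ± 0.16) and Klhl26 (-2.29 ± 0.08) were among the genes that fell. Against Control 1432 genes rose and 1411 fell, 638 of them at least 2-fold.

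SFSN-FB differed from the other SFSN groups in more genes than any other group did, with 798 higher and 811 lower. Inflammatory cytokine genes were higher, 10 of 12 (11 adjusted over the list alone), with Il6 at 1.39 ± 0.08, Cxcl1 at 1.07 ± 0.07 and a median of 0.87 (adjusted p = 1.09e-18, and adjusted p = 0.00134 with an estimated correlation). Interferon response genes had a median of 0.36 with 2 of 10 called higher, among them Ifit2 (0.81 ± 0.04), at adjusted p = 0.00155 and adjusted p = 0.0336 with an estimated correlation. In the list of the unfolded protein and amino acid response 5 of 9 rose (6 adjusted over the list alone), among them Atf3 (1.18 ± 0.05), Herpud1 (0.64 ± 0.04) and the asparagine synthetase Asns (0.38 ± 0.04). The list had a median of 0.32 (adjusted p = 2.53e-08, and adjusted p = 0.0325 with an estimated correlation). TGF-beta and YAP targets had 5 higher and 1 lower of 8, with Bhlhe40 at 1.13 ± 0.07 and a median of 0.29 (adjusted p = 0.0011, and adjusted p = 0.0155 with an estimated correlation). Ass1 rose by 1.84 ± 0.13 and the receptor gene Gpr84 of myeloid cells by 1.36 ± 0.10, beside Csf1r at 0.59 ± 0.04. Fat genes fell relative to the other SFSN groups, with Gpd1 at -2.26 ± 0.12, Fabp4 at -1.99 ± 0.18, Adipoq at -1.87 ± 0.11, 9 of 14 adipocyte genes lower (1 higher and 10 lower adjusted over the list alone) and a median of -0.57 (adjusted p = 4.75e-10, and adjusted p = 0.00482 with an estimated correlation). Notch pathway genes fell, 4 of 8, with Hey1 at -1.24 ± 0.12 and a median of -0.26 (adjusted p = 0.00094, and adjusted p = 0.0324 with an estimated correlation), and cell cycle genes 9 of 12, with Ccna2 at -0.30 ± 0.04 and a median of -0.27 (adjusted p = 0.00106, and adjusted p = 0.0137 with an estimated correlation). The p53 and senescence list was higher, 4 of 8 (5 adjusted over the list alone), with Cdkn2b at 0.49 ± 0.04 and a median of 0.23 (adjusted p = 0.0118, and adjusted p = 0.0412 with an estimated correlation). Cholesterol synthesis genes rose, 6 of 11. Their median was 0.17 (adjusted p = 0.00129, and adjusted p = 0.0325 with an estimated correlation).

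In SFSN-Neu, neuronal genes were not higher than in Control. Of the 5 tested, Map2 fell by -1.10 ± 0.14 and the glutamate receptor gene Gria2 by -0.57 ± 0.20, and Eno2 (-0.85 ± 0.64), the migrating-neuron marker Dcx (-0.52 ± 0.33) and the postsynaptic scaffold gene Dlg4 (-0.25 ± 0.18) were not called. The list's median was -0.57 (adjusted p = 0.222), and relative to the other SFSN groups it was -0.24 (adjusted p = 0.612). Without SFSN-Neu 2 these were -0.30 (adjusted p = 0.526) and -0.10 (adjusted p = 0.974). Gria2 lost its call without SFSN-Neu 2 (-0.38, adjusted p = 0.165), SFSN-Neu 3 (adjusted p = 0.0629), Control 1 (adjusted p = 0.0901) or Control 3 (adjusted p = 0.135). It was not called under total-count scaling (adjusted p = 0.15) or with DESeq2 either (adjusted p = 0.0507). The separate list of synaptic and ion channel genes had 2 higher and 2 lower of 8 (2 and 3 adjusted over the list alone) and a median of 0.17, with the direction of the test downward (adjusted p = 0.75). In it the potassium channel gene Kcnd3 fell by -1.12 ± 0.15 and the calcium channel gene Cacna1a rose by 0.91 ± 0.16.

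Macrophage and leukocyte genes were higher in SFSN-Neu. Against Control 10 of 13 rose (11 adjusted over the list alone). Their median was 0.92 (adjusted p = 7.58e-11, and adjusted p = 0.00613 with an estimated correlation). Csf1r, the receptor of the macrophage growth factor, rose by 1.52 ± 0.05, from 91.3 to 262 CPM, the macrophage surface gene Adgre1 by 2.61 ± 0.10, Itgam by 1.52 ± 0.15 and the complement gene C1qb by 1.22 ± 0.23. Single bone, matrix and fat genes also rose, with Ibsp at 4.75 ± 0.10, Adipoq at 3.81 ± 0.18, Acan at 3.50 ± 0.14 and Enpp2 at 3.16 ± 0.17. The osteoblast list had a median of 0.35 with 4 higher and 1 lower of 8 (adjusted p = 9.63e-05, and adjusted p = 0.00821 with an estimated correlation), and the adipocyte list a median of 0.66 with 9 higher and 1 lower of 14 (10 and 1 adjusted over the list alone, adjusted p = 2.96e-06, and adjusted p = 0.0202 with an estimated correlation). Inflammatory cytokine genes had 8 higher and 1 lower of 12 (8 and 2 adjusted over the list alone) and a median of 1.09 (adjusted p = 4.44e-06, and adjusted p = 0.0454 with an estimated correlation). The chemokine genes that rose included Cxcl13 (5.49 ± 0.23), Cxcl1 (3.01 ± 0.13), Cxcl14 (2.90 ± 0.21) and Ccl20 (2.73 ± 0.21). The 8 TGF-beta and YAP targets were called lower, with Bhlhe40 at -1.23 ± 0.10, the receptor kinase gene Axl at -0.90 ± 0.16 and a median of -0.50 (adjusted p = 0.000927, and adjusted p = 0.0156 with an estimated correlation). Of the 8, Ankrd1 (-0.66 ± 0.23) lost its call without Control 2 (-0.38, adjusted p = 0.282), SFSN-Neu 1 (adjusted p = 0.0977) or SFSN-Neu 3 (adjusted p = 0.07), and with DESeq2 (adjusted p = 0.0588). The falls included those of Dio3 (-3.86 ± 0.22), Egfl6 (-3.13 ± 0.20), Flt1 (-2.78 ± 0.16), Lvrn (-2.47 ± 0.09), Esm1 (-2.23 ± 0.06) and the skeletal actin gene Acta1 (-2.01 ± 0.16). Against Control 1340 genes rose and 1194 fell, 556 of them at least 2-fold.

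Among the SFSN groups, 12 of the 13 macrophage and leukocyte genes were higher in SFSN-Neu. Their median was 0.57 (adjusted p = 1.3e-22, and adjusted p = 0.000187 with an estimated correlation). Csf1r rose by 0.97 ± 0.03, C1qb by 0.90 ± 0.16, the lysosomal gene Laptm5 by 0.66 ± 0.06 and Lyz2 by 0.41 ± 0.06. Other genes active in leukocytes that rose included Klhl6 (1.22 ± 0.18), Ly86 (1.17 ± 0.21), the fractalkine receptor Cx3cr1 (1.03 ± 0.11) and Dock2 (1.01 ± 0.07). Immediate early genes were lower, 10 of 12 (11 adjusted over the list alone), with Egr3 at -1.55 ± 0.15, Egr2 at -1.20 ± 0.08, Dusp1 at -0.62 ± 0.03 and a median of -0.54 (adjusted p = 6.07e-24, and adjusted p = 4.4e-05 with an estimated correlation). The list of the unfolded protein and amino acid response had 3 of 9 lower (1 higher and 6 lower adjusted over the list alone), with Atf3 at -1.07 ± 0.06 and a median of -0.22 (adjusted p = 3.07e-08, and adjusted p = 0.0325 with an estimated correlation). TGF-beta and YAP targets had 4 of 8 lower (1 higher and 5 lower adjusted over the list alone) and a median of -0.22 (adjusted p = 2.09e-05, and adjusted p = 0.00355 with an estimated correlation), and the p53 and senescence list 4 of 8 lower (1 higher and 5 lower adjusted over the list alone), with Btg2 at -0.75 ± 0.04 and a median of -0.21 (adjusted p = 1.46e-05, and adjusted p = 0.00325 with an estimated correlation). Cxcl1 (-1.44 ± 0.09) and Il6 (-0.93 ± 0.09) fell. A total of 446 genes rose and 365 fell, and the 811 became 428 without SFSN-Neu 2, the library that stood apart from its group, and 540 without SFSN-Neu 3.

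In SFSN-Adipo, adipocyte genes were higher than in Control and higher than the mean of the other SFSN groups. Of 14 tested, 11 rose and 1 fell against Control. Adipoq rose by 4.32 ± 0.17, from 1.47 to 29.7 CPM, Fabp4 by 3.84 ± 0.23, the adipsin gene Cfd by 2.94 ± 0.19, Cd36 by 2.08 ± 0.11, the hormone-sensitive lipase gene Lipe by 2.06 ± 0.19 and the lipoprotein lipase gene Lpl by 1.19 ± 0.06, while the fatty acid synthase gene Fasn fell by -0.25 ± 0.07. Cidec, a lipid droplet gene with 1 to 3 counts per Control library, was 15.4 times its Control level (6.84 to 42.9). Cebpb (0.11 ± 0.11) and Acaca (0.39 ± 0.31) were not called. The leptin gene Lep had too few counts to be tested. It had 15, 14 and 7 counts in the Control libraries and 5, 2 and 1 in those of SFSN-Adipo. The median was 1.12 (adjusted p = 2.9e-11, and adjusted p = 0.0051 with an estimated correlation). Relative to the other SFSN groups 7 members rose (8 adjusted over the list alone), among them Fabp4 (0.87 ± 0.14), Cd36 (0.48 ± 0.08), Adipoq (0.41 ± 0.09) and Lpl (0.21 ± 0.04). Of the 7, Lipe (0.42 ± 0.13) lost its call without SFSN-Adipo 1, 2 or 3 (adjusted p = 0.205, 0.153 and 0.0774) and without a low-count filter (adjusted p = 0.0604), and Cfd (0.52 ± 0.12) lost it without SFSN-Adipo 1 (adjusted p = 0.084). The median of the list was 0.38 (adjusted p = 4e-06, and adjusted p = 0.026 with an estimated correlation), and 0.24 without SFSN-Adipo 1 (adjusted p = 0.000319). SFSN-TC and SFSN-EC were also higher than their own mean of other groups in this list, with medians of 0.68 and 0.33.

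Further rises in SFSN-Adipo, which other SFSN groups shared, included Cxcl13 at 4.93 ± 0.24, Aqp7 at 4.44 ± 0.26, Ibsp at 4.31 ± 0.10, Cxcl1 at 3.93 ± 0.13, Gpd1 at 3.81 ± 0.16 and Acan at 3.53 ± 0.14. Cell cycle genes rose, 9 of 12 (10 adjusted over the list alone), with Kif11 at 0.81 ± 0.10, Aurkb at 0.64 ± 0.08 and a median of 0.40 (adjusted p = 0.000777, and adjusted p = 0.0145 with an estimated correlation). Macrophage and leukocyte genes had a median of 0.58 with 8 of 13 higher (9 adjusted over the list alone), among them Adgre1 (2.50 ± 0.10) and Laptm5 (0.73 ± 0.08), at adjusted p = 1.57e-05 and adjusted p = 0.0364 with an estimated correlation. The osteoblast list had 2 higher and 2 lower of 8 (3 and 2 adjusted over the list alone) and a median of 0.34 (adjusted p = 0.00132, and adjusted p = 0.0176 with an estimated correlation), and the inflammatory cytokine list 7 higher and 1 lower of 12 and a median of 0.56 (adjusted p = 3.91e-06, and adjusted p = 0.0412 with an estimated correlation). The 8 TGF-beta and YAP targets were called lower. Their median was -0.48 (adjusted p = 0.000927, and adjusted p = 0.0156 with an estimated correlation). Of the 8, Ankrd1 (-0.62 ± 0.23) lost its call without Control 2 (-0.35, adjusted p = 0.33), SFSN-Adipo 1 (adjusted p = 0.16) or SFSN-Adipo 3 (adjusted p = 0.0685), and with DESeq2 (adjusted p = 0.0736). Dio3 (-3.20 ± 0.21), Egfl6 (-3.04 ± 0.19), F2rl1 (-2.78 ± 0.17), Lvrn (-2.62 ± 0.09), Flt1 (-2.50 ± 0.16) and Dusp14 (-2.03 ± 0.09) were among the genes that fell. Against Control 1309 genes rose and 1121 fell, 496 of them at least 2-fold.

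Compared with the other SFSN groups, SFSN-Adipo had lower bone genes, with Ibsp at -0.55 ± 0.06 and an osteoblast median of -0.25 (3 of 8 lower, 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.00822, and adjusted p = 0.034 with an estimated correlation). Chac1 rose by 1.09 ± 0.08, the receptor kinase gene Ephb3 by 0.69 ± 0.07 and Cilp2 by 0.67 ± 0.09, and Arl4c fell by -0.94 ± 0.04, Gcnt2 by -0.74 ± 0.05 and Gprc5a by -0.66 ± 0.09. Immediate early genes had 7 lower and 1 higher of 12, with Fosl1 at -0.63 ± 0.08, Dusp6 at -0.59 ± 0.05 and a median of -0.29 (adjusted p = 4.17e-06, and adjusted p = 0.00607 with an estimated correlation). TGF-beta and YAP targets fell, 5 of 8, with Bhlhe40 at -0.70 ± 0.08 and a median of -0.18 (adjusted p = 4.17e-06, and adjusted p = 0.00219 with an estimated correlation), and the cell cycle list had a median of 0.13 with 2 of 12 higher (5 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.0396 with an estimated correlation). Lyz2 stood at 0.45 ± 0.06, and the macrophage and leukocyte list at a median of 0.15 (3 of 13 higher, 4 adjusted over the list alone, adjusted p = 0.00741), a call lost with adjusted p = 0.167 with an estimated correlation. The 698 genes called (380 higher, 318 lower) became 437, 391 and 400 without SFSN-Adipo 1, 2 and 3.

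**Figure D2:**
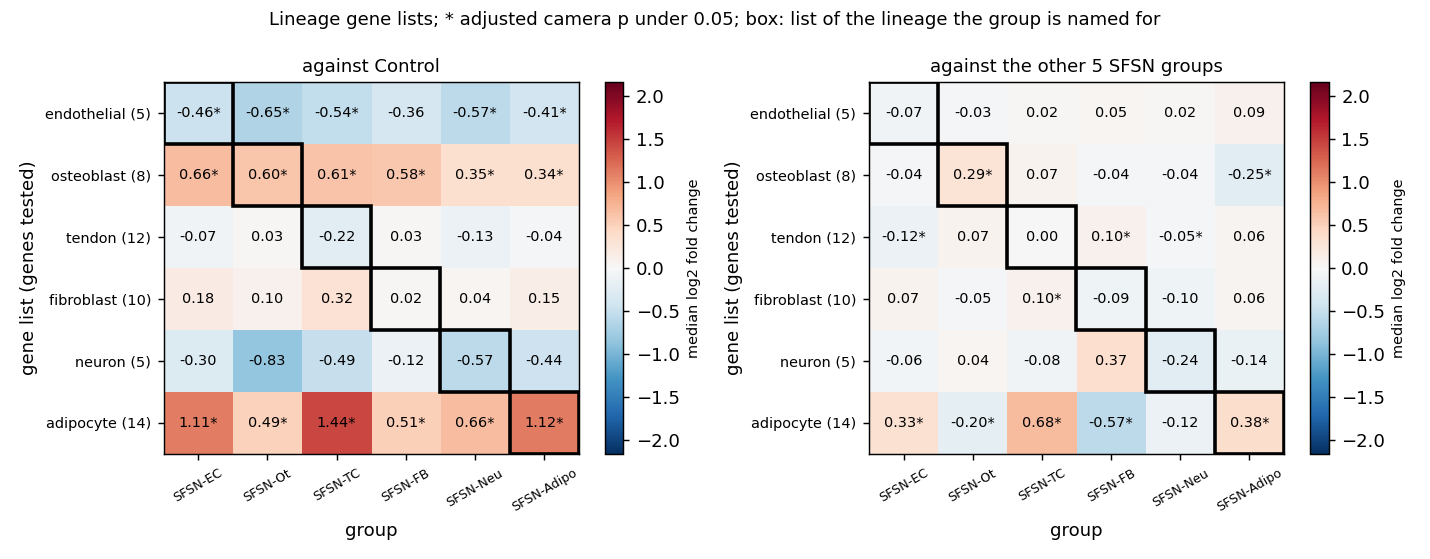
Median log2 fold change of the tested genes of 6 lineage lists (vertical) in each SFSN group (horizontal), left against Control and right against the mean of the other 5 SFSN groups, with a star for an adjusted camera p under 0.05 and a box around the list of the fate that gives the group its name. Adipocyte and osteoblast medians are above 0 in all 6 groups against Control (0.49 to 1.44 and 0.34 to 0.66), the endothelial median is below 0 in all 6 (-0.65 to -0.36), and among the boxes on the right those of SFSN-Ot (0.29) and SFSN-Adipo (0.38) carry a star.

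A common set of genes moved the same way in every SFSN group. Against Control 566 genes were called higher in all 6 groups and 597 lower, 27.5% of the 4227 genes called in any of them, and 128 and 71 of these changed at least 2-fold in each. Among the shared rises were Cxcl13 (4.44 to 5.79), Ibsp (4.31 to 5.18), Acan (3.50 to 3.93), Cxcl1 (3.01 to 5.11), Enpp2 (2.76 to 3.67), Aqp7 (2.69 to 5.04), the protease gene Adamts15 (2.47 to 3.41) and Asic3 (2.43 to 2.89). Aggrecan was also abundant, at 105 CPM in Control. Among the shared falls, Dio3 fell by 3.20 to 5.18 on the log2 scale, Egfl6 fell by 2.63 to 3.19, Flt1 fell by 2.50 to 2.78, Lvrn fell by 2.06 to 2.62, Cd55 fell by 1.87 to 2.35, Esm1, an endothelial proteoglycan gene, fell by 1.73 to 2.30, and Map1b, a microtubule protein of neurons, fell by 1.62 to 1.97. A further 198 genes rose in some groups and fell in others. Dll1, a Notch ligand with 1 to 3 counts per Control library, was 14 times (6.16 to 39) its Control level in SFSN-FB and 34.3 times (15.5 to 94.4) in SFSN-EC. Cxcl6, with 1 count per Control library, ranged from 4.73 times (1.35 to 25.3) in SFSN-TC to 27.3 times (9.03 to 135) in SFSN-FB.

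All 6 comparisons used the same 3 Control libraries. In 20 simulations of unchanged groups with a shared, simulated Control, 0 genes were shared by all 6. Lists drawn independently would share 0.39 higher and 0.24 lower genes. Fold changes correlated between pairs of groups with a mean of 0.778 across genes (0.646 to 0.847), where the simulations gave 0.499, and their mean covariance was 0.441 (0.389 to 0.515), where the simulations gave 0.069. SFSN-EC and SFSN-TC shared 969 higher genes, where independent lists would share 227.5, and SFSN-Ot and SFSN-FB shared 1138, where independent lists would share 289.7. With 3 Control libraries no split leaves 2 in each part, so part of the excess may come from the shared controls. Total-count scaling shifted the median of all genes by 0.16 to 0.22 and moved the split of higher against lower calls. The share of calls that were higher was 53.2% in SFSN-EC, 51.2% in SFSN-Ot, 50.7% in SFSN-TC, 50.4% in SFSN-FB, 52.9% in SFSN-Neu and 53.9% in SFSN-Adipo, and under total-count scaling it was 81.7%, 74.3%, 78.3%, 75%, 81.2% and 82.5% in the same order. The genes shared by all 6 were then 1294 higher and 306 lower.

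**Figure D3:**
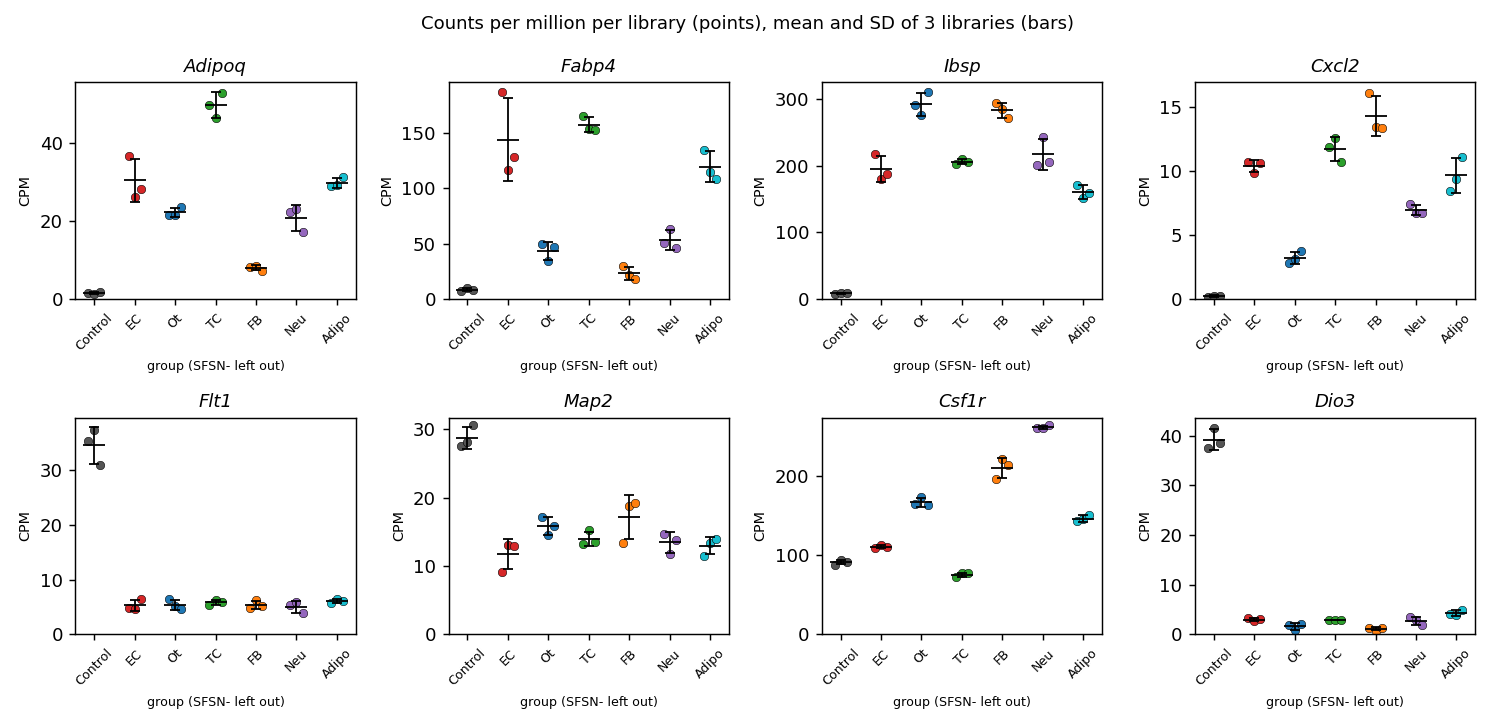
CPM of 8 genes (vertical) in each library of the 7 groups (horizontal), 1 point per library with the group mean and SD of 3 libraries. Ibsp stands at 8.06 CPM in Control and at 161 to 293 in the SFSN groups, Flt1 at 34.6 and at 5.02 to 6.08, and Csf1r ranges from 75.3 in SFSN-TC to 262 in SFSN-Neu.

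Pairs of SFSN groups differed unequally. SFSN-EC and SFSN-TC, named for endothelial and tendon cells, differed in 111 genes, SFSN-EC and SFSN-Adipo in 254 and SFSN-Ot and SFSN-FB in 305, whereas SFSN-TC and SFSN-FB differed in 1863, SFSN-FB and SFSN-Adipo in 1558 and SFSN-EC and SFSN-FB in 1439. The other 9 pairs lay between 379 (SFSN-Neu and SFSN-Adipo) and 1350 (SFSN-Ot and SFSN-TC). With SFSN-EC 1 and SFSN-Neu 2 left out, the genes called against Control numbered 2647 in SFSN-EC, 3156 in SFSN-Ot, 3122 in SFSN-TC, 3322 in SFSN-FB, 2744 in SFSN-Neu and 2956 in SFSN-Adipo. Relative to the mean of the other SFSN groups they were then 403, 1262, 1246, 2107, 635 and 915 in the same order.

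The remaining lists were tested in the same way, and their ranges run over the 6 groups. Heat shock genes fell against Control in all 6 groups, with 8 to 10 of 12 lower (9 to 12 adjusted over the list alone), medians of -0.70 to -0.41 and adjusted p = 3.02e-07 to 0.00276, and the calls were lost with adjusted p = 0.125 to 0.382 with an estimated correlation. The chaperone gene Hsph1 fell by -0.68 ± 0.05 in SFSN-FB and -0.97 ± 0.05 in SFSN-EC, and the co-chaperone Bag3 by -0.74 ± 0.10 in SFSN-EC and -0.89 ± 0.10 in SFSN-FB. Chondrocyte genes had medians of 0.13 to 0.48 and adjusted p = 0.0147 to 0.0476, calls lost with adjusted p = 0.0574 to 0.116 with an estimated correlation. Acan was called higher in all 6 groups and Col9a2 lower (-0.80 ± 0.10 in SFSN-Adipo). Without Control 1 or Control 2 and with a filter of 1 CPM in 3 libraries no chondrocyte list kept its call, and with that filter the medians of all groups but SFSN-EC turned negative (-0.74 in SFSN-Adipo, adjusted p = 0.165). The call of SFSN-Adipo was also lost without Control 3 (adjusted p = 0.061). Each group lost the call, with a negative median, when some of its own libraries were left out: SFSN-EC 2 (-0.33, adjusted p = 0.0735), SFSN-Ot 1 and 2 (-0.56 and -0.18, adjusted p = 0.0594 and 0.0818), SFSN-TC 1, 2 and 3 (-0.52, -0.63 and -0.25, adjusted p = 0.0844, 0.0905 and 0.0956), SFSN-FB 1 and 3 (-0.42 and -0.35, adjusted p = 0.0642 and 0.0652), SFSN-Neu 1, 2 and 3 (-0.27, -0.56 and -0.40, adjusted p = 0.0666, 0.066 and 0.0766) and SFSN-Adipo 1, 2 and 3 (-0.52, -0.63 and -0.80, adjusted p = 0.129, 0.144 and 0.145). The chondrocyte result was thus not stable. Smooth muscle genes fell in SFSN-Neu (adjusted p = 0.0223, and adjusted p = 0.294 with an estimated correlation) and SFSN-Adipo (adjusted p = 0.00732, and adjusted p = 0.225 with an estimated correlation), and the calponin gene Cnn1 by -0.73 ± 0.12 in SFSN-Ot and -1.10 ± 0.12 in SFSN-Adipo. Genes of the mesenchymal stem cell surface and niche fell in SFSN-TC, SFSN-Neu and SFSN-Adipo (medians -0.21, -0.11 and -0.14), calls lost with adjusted p = 0.0659 to 0.0966 with an estimated correlation and under total-count scaling, which turned the medians of SFSN-Neu and SFSN-Adipo to 0.10 and 0.07. In that list Cxcl12, the niche chemokine, fell by -0.71 ± 0.03 in SFSN-EC and -0.99 ± 0.04 in SFSN-TC.

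Hypoxia and glycolysis genes fell in SFSN-TC (6 of 9 lower, 1 higher and 8 lower adjusted over the list alone, median -0.48, adjusted p = 0.0147, and adjusted p = 0.294 with an estimated correlation), and interferon response genes fell there too (median -0.51, adjusted p = 0.0319, and adjusted p = 0.132 with an estimated correlation), a call also lost with SFSN-EC 1 and SFSN-Neu 2 left out (adjusted p = 0.0791) and with the gene-length trend taken out (adjusted p = 0.0846). BMP targets (medians -0.18 to 0.22, adjusted p = 0.134 to 0.926), Wnt targets (0.00 to 0.36, adjusted p = 0.344 to 0.919), genes of matrix remodelling (-0.02 to 0.41, adjusted p = 0.489 to 0.99), mitochondrial respiration (-0.28 to -0.05, adjusted p = 0.393 to 0.919) and glia and Schwann cells (2 tested, -0.45 to 0.19, adjusted p = 0.78 to 0.999) were not called against Control in any group. Single BMP genes moved in both directions. In SFSN-EC Bmp4 stood at -1.47 ± 0.17 and Bmp6 at -1.98 ± 0.16, while Bmp5, outside the list, was called higher in all 6 groups (1.08 to 1.72). Median, mean and test differed in sign for the BMP, tendon and fibroblast lists in 4 of the 6 groups each and for the synaptic list in 5. Of the epithelial list a single gene, Krt8, had enough counts, with 0.02 ± 0.26 in SFSN-EC and no call in any group. Of the 9 erythroid genes, 8 were in the table and none had enough counts to be tested. The 20 tested genes of the markers that the submitters set beside their table had medians of 0.11 to 0.19 with 8 to 9 higher and 6 to 8 lower against Control (8 to 10 and 6 to 8 adjusted over the list alone, adjusted p = 0.00063 to 0.0176, and adjusted p = 0.00362 to 0.0214 with an estimated correlation). That list may have been chosen on these samples and is not independent evidence. Over all list results, 217 of 324 had an equal count adjusted over the list alone, 106 a higher one, by at most 4 genes, and 1 a lower one, by 1.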

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

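The tests of the scaling of the libraries in the first pattern and of gene length in the third were chosen after the result was seen, as were total-count scaling, the authors' library factors, the omission of SFSN-EC 1 and SFSN-Neu 2 and the gene-length trend.

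The first pattern was that the adipocyte and osteoblast lists were called higher than Control in every SFSN group at the preset correlation. Not all of their members rose. Of 14 adipocyte genes 8 to 11 rose and 1 to 2 fell, depending on the group. Of 8 osteoblast genes 2 to 4 rose and 1 to 2 fell. Over all genes, the mean covariance of fold changes between groups exceeded that of simulated unchanged groups with a shared Control by 0.372. The spread between replicates of a shared Control therefore does not account for all of that covariance. The simulation drew Control anew and did not look at the lists. It thus cannot decide whether a shift of the real Control libraries lies behind the pattern. The scaling of a library moves all its genes alike, and in 10 of the 12 results the list median exceeded the median of all genes by at least 0.32 and was called with either correlation, which argues against scaling as the cause there. For the adipocyte list in SFSN-Ot and SFSN-FB the excess was at least 0.49, which a factor per library would leave unchanged. The call was lost with an estimated correlation (adjusted p = 0.055 and 0.212). This leaves the excess itself uncertain, so the test cannot decide on scaling for these. With total counts, RLE or the authors' factors, all 36 results of both lists stayed called at the preset correlation (lowest median 0.33, highest adjusted p = 0.0398, camera). Camera sets a list against all other genes, and a factor per library moves both alike. These calls could therefore change little, and they add no evidence on scaling. With the gene length trend taken out the lowest median was 0.29 and all 12 results were called at the preset correlation, which argues against length bias as the whole cause. The labels name no batch, and an effect of the SFSN treatment, which the design names, stays open as a hypothesis.

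The second pattern was that macrophage and leukocyte genes were higher in SFSN-Neu than in the other SFSN groups. Leaving out 1 SFSN-Neu library in turn gave a median of at least 0.46, and taking out the gene length trend gave 0.50, so neither a single library nor length bias was the whole cause. Among 100 relabelings of the 18 SFSN libraries, 1, the real one, gave the list as small a camera p (minus log10 p 23.79, highest other 13.48). The SFSN-Neu libraries were thus more alike in this list than random sets were. Chance is not excluded, since the list was picked in these same data and the replicates may be technical. A second list of 32 leukocyte genes, written before the test and without a gene of the first, had 31 tested, 21 higher and a median of 0.48 (adjusted p = 1.91e-31, and adjusted p = 3.04e-06 with an estimated correlation). Lcp1 stood at 144 CPM in Control, 330 in SFSN-Neu and 319 in SFSN-FB, Coro1a at 50.6, 156 and 148. Cd48, which was not called, stood at 142, 160 and 151. This list was tested against the other SFSN groups and not against Control. Some members had a lower mean in SFSN-Neu than in Control. They were Gpnmb (416 and 524 CPM), Clec7a (14.6 and 17.2), Csf2ra (8.9 and 9.6), Il10ra (4.8 and 7.3), Cd33 (4.2 and 5.8), Clec4a (2.8 and 3.7) and Cd84 (1.8 and 3.4). The other members had a higher mean. The second list was also called higher in SFSN-FB (13 of 31, median 0.24, adjusted p = 0.00224 with an estimated correlation) and SFSN-Adipo (median 0.17, adjusted p = 0.0245 with an estimated correlation). The second list was called lower in SFSN-EC (11 of 31, median -0.26, adjusted p = 3.02e-05 with an estimated correlation). It was lower in SFSN-TC too (17 of 31, median -0.36, adjusted p = 1.52e-05 with an estimated correlation). More macrophages among the SFSN-Neu cells are a candidate explanation that would not be particular to that group. A change of these genes within the stem cells stays open as well. Control libraries held counts of all 31, from a mean of 1.1 CPM for Cd86 to 524 for Gpnmb. RNA of whole cultures does not show which cells these came from, so the Control values do not decide between the explanations.

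The third pattern was that the libraries SFSN-EC 1 and SFSN-Neu 2 stood apart from their groups. In both, long genes were low relative to short ones when set against the other libraries of the group, by -0.74 and -0.50 on the log2 scale between the longest and the shortest of 5 equal classes of genes, where the other 19 libraries lay between -0.43 and 0.38. Exchanged labels were argued against by their position on the way to the other group, at most 0.16 where 0 is the own group and 1 the other. A difference in RNA or library quality that acts on long transcripts may therefore be behind the distance of these 2 libraries, and how the libraries differed in the laboratory is not given in the sources used here.

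With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the most genes in each comparison with Control. The real and highest other counts were 2215 and 428 for SFSN-EC, 2632 and 0 for SFSN-Ot, 2534 and 0 for SFSN-TC, 2843 and 1 for SFSN-FB, 2534 and 0 for SFSN-Neu and 2430 and 0 for SFSN-Adipo. Against the other SFSN groups, 100 relabelings of the 18 libraries, the real one included, were compared by the number of genes called. For each group the median of the others was 0. Few gave as many genes as the real grouping, so libraries of a group resembled each other more than most random sets did. Relabelings mix the groups, which widens the spread, and replicates may be technical, so chance differences between cultures were not excluded. The real relabeling alone, 1 of 100, gave as many genes for SFSN-Ot (999, highest other 405), SFSN-TC (1036 and 248), SFSN-FB (1609 and 857) and SFSN-Adipo (698 and 1), and 2 did for SFSN-EC (400 and 2298) and SFSN-Neu (811 and 919). The relabeling with 2298 genes joined SFSN-EC 1, SFSN-FB 1 and SFSN-Neu 2, the 3 libraries with the strongest decline over gene length, and points to a structure of the samples that runs across the groups.

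The remaining results stood out because a test of the difference between groups was passed, and no explanation of them was tested. Relative to the mean of the other SFSN groups, the adipocyte median was 0.33 in SFSN-EC, -0.20 in SFSN-Ot, 0.68 in SFSN-TC, -0.57 in SFSN-FB and 0.38 in SFSN-Adipo. The macrophage and leukocyte median was -0.18 in SFSN-EC, -0.30 in SFSN-TC and 0.57 in SFSN-Neu. Cholesterol synthesis genes stood at -0.29 in SFSN-EC, 0.28 in SFSN-Ot, -0.27 in SFSN-TC and 0.17 in SFSN-FB, and immediate early genes at 0.26 in SFSN-EC, 0.34 in SFSN-TC, -0.54 in SFSN-Neu and -0.29 in SFSN-Adipo. TGF-beta and YAP targets stood at 0.29 in both SFSN-Ot and SFSN-FB, -0.22 in SFSN-Neu and -0.18 in SFSN-Adipo, and cell cycle genes at -0.15 in SFSN-Ot, -0.27 in SFSN-FB and 0.13 in SFSN-Adipo. Osteoblast genes had 0.29 in SFSN-Ot and -0.25 in SFSN-Adipo, and Notch pathway genes 0.34 in SFSN-TC and -0.26 in SFSN-FB. The p53 and senescence list had 0.23 in SFSN-FB and -0.21 in SFSN-Neu, and the unfolded protein and amino acid response 0.32 in SFSN-FB and -0.22 in SFSN-Neu. In SFSN-FB the inflammatory cytokine median was 0.87 and the interferon response median 0.36, and in SFSN-EC the BMP target median was 0.19.

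Only genes picked by the rules for naming genes were searched here, and 12 of them were called in opposite directions against Control in 2 groups, with a called difference between those groups. SFSN-FB and SFSN-TC differed in Alox5 by 3.40 ± 0.22 (2.19 and -1.21 against Control, adjusted p = 2.15e-09), in Gpr84 by 2.59 ± 0.16 (1.44 and -1.15, adjusted p = 8.63e-10) and in Adam8 by 2.23 ± 0.08 (1.77 and -0.47, adjusted p = 1.42e-12). SFSN-Neu and SFSN-TC differed in Dock2 by 2.04 ± 0.10 (1.67 and -0.38, adjusted p = 6.66e-11), in Csf1r by 1.80 ± 0.05 (1.52 and -0.28, adjusted p = 5.55e-14) and in Klhl6 by 1.78 ± 0.26 (1.04 and -0.75, adjusted p = 8.14e-05). Chac1 differed by 2.19 ± 0.11 between SFSN-Adipo (0.56) and SFSN-Ot (-1.63, adjusted p = 2.47e-10), Egr2 by 1.72 ± 0.10 between SFSN-FB (0.93) and SFSN-Neu (-0.79, adjusted p = 1.81e-09), and Arl4c by 1.54 ± 0.05 between SFSN-FB (0.61) and SFSN-Adipo (-0.93, adjusted p = 2.88e-13). Frmd6 differed by 1.10 ± 0.05 between SFSN-Ot (0.31) and SFSN-Adipo (-0.79, adjusted p = 1.65e-10), Cilp2 by 1.04 ± 0.12 between SFSN-Adipo (0.53) and SFSN-TC (-0.52, adjusted p = 1.53e-05), and Creb5 by 0.96 ± 0.10 between SFSN-Ot (0.65) and SFSN-Adipo (-0.31, adjusted p = 1.84e-06).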

How the results depend on the processing

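Total-count scaling, the authors' library factors, the omission of SFSN-EC 1 and SFSN-Neu 2 and the gene-length trend were added after the results were seen. Each alternative named in the methods was run, and the cause of a change was not tested. The labels do not say whether replicate numbers pair libraries across groups. With group means taken out, libraries of different groups correlated with a median of 0.01 for the same number (-0.48 to 0.53). For different numbers the median was 0.02 (-0.46 to 0.63). Of the 21 libraries, 10 correlated best with those of their own number. Pairing was thus neither shown nor excluded. With an estimated correlation the endothelial list of SFSN-EC kept its median of -0.456 against Control but lost its call (adjusted p = 0.132). Among the 94 list results that the fry test called and camera did not were tendon in SFSN-TC (-0.222, adjusted p = 0.0213), fibroblast in SFSN-FB (0.021, adjusted p = 0.0177, and -0.086 relative to the other SFSN groups, adjusted p = 0.0113) and neuron in SFSN-Neu (-0.570, adjusted p = 0.000785). Without SFSN-EC 1 and SFSN-Neu 2, SFSN-Ot and SFSN-FB differed in 468 genes and the fibroblast list of SFSN-FB was called at -0.098. With the gene-length trend out, SFSN-EC had 645 genes relative to the other SFSN groups, and the pairs SFSN-EC and SFSN-Adipo, SFSN-Ot and SFSN-FB, and SFSN-Neu and SFSN-Adipo had 406, 481 and 582. SFSN-Ot had 656 genes relative to the others on log2 TPM with either added value, and SFSN-EC had 1381 against Control with only its 6 libraries. Leave-one-out ranges relative to the others were 250 (without SFSN-EC 2) to 323 for SFSN-EC, with 253 without SFSN-EC 3, 657 to 667 for SFSN-Ot, 599 to 647 for SFSN-TC, 428 (without SFSN-Neu 2) to 542 for SFSN-Neu and 391 to 437 for SFSN-Adipo. Changes of sign were few. Total-count scaling gave Lmod1 in SFSN-Ot 0.004, Ldha in SFSN-Neu 0.047 and Col1a1 in SFSN-Adipo 0.037. On log2 TPM with 1 added, Dcx had 0.062 in SFSN-EC, 0.070 in SFSN-TC and 0.006 in SFSN-Adipo, Lmod1 0.013 and Col1a1 0.042, and with 0.1 added 0.066, 0.073, 0.007, 0.014 and 0.042. Of 18831 values for single genes, 17939 held their call, 879 lost it and 13 changed sign. Of the fixed lists, 67 results were called against Control and 63 relative to the other SFSN groups, and with an estimated correlation as well 29 and 34 of them. With 3 libraries per group, 53.7% of simulated 1.5-fold changes against Control were called, so smaller changes are under-represented.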

Other observations

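Among the single genes called lower in all 6 SFSN groups, Map1b fell by 1.62 to 1.97 on the log2 scale and Esm1 by 1.73 to 2.30. Lox, which crosslinks collagen, went from 4857 CPM in Control to between 1931 and 2380 CPM in the SFSN groups.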
